A study of Mus musculus with 6 samples.

How the data were processed

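The series holds 6 Affymetrix 3' expression arrays of the Mouse Genome 430 2.0 type, as the probe table names the platform. Each array was hybridised with total RNA from small intestinal stem cells of 1 mouse carrying an EGFP and CreERT2 cassette in the Lgr5 gene. Cells with high GFP were sorted from mice given vehicle (DMSO) or DBZ, an inhibitor of gamma-secretase, and collected at 24 h. There were 3 vehicle and 3 DBZ mice, called biological replicates in the sample titles. The titles put each array in its group. The description field names DMSO for all 6 arrays, and so disagrees with the titles of 3 of them. The labels write the DBZ dose as 30 mol per kg, a unit that has probably lost its prefix, so the dose is not used here.

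Per the labels, RNA was amplified and biotin-labelled with a 3' IVT kit. The authors' deposited values are probe set intensities on a linear scale, already on a common level between arrays. The software and the method of background correction and normalization are not given in the sources used here, and neither are detection calls. Array medians lay between 44.9 and 46.3, and the highest intensities between 27330 and 29871. The number of arrays limits the precision of every value.

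Of 45101 probe sets, 64 were array controls. A single gene symbol was given for 34958, several symbols for 932 and none for 9160 outside the controls. Of those with a single symbol 13 were array controls, which were left out of the tests. The Entrez identifiers of 34754 single-symbol probe sets were found in the reference gene table, and this changed 0 symbols. Probe sets with several symbols or none were left out of the tests by gene. A gene was represented by its probe set with the highest mean log2 value over the 6 arrays, which gave 18193 genes. Among the genes named, 9 have another probe set of opposite sign, none of them past the threshold. No genome was used, so positions are not given.

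Intensities were tested as log2(intensity + 16). A fold change on this scale understates the change of dim genes. The 6 array medians differed by less than 0.1 on that scale, the limit set for keeping values as deposited, so they were not normalized again. DBZ was compared with vehicle by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SE is the moderated standard error, and SD is given for intensities with n = 3 mice per group. The prior contributed 2.21 degrees of freedom. An exact permutation test of a single value in this design cannot go below p = 0.1.

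Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 33 lists with at least 5 measured members. Of 561 genes in 34 lists, 511 were measured. camera with a correlation estimated for each list, and fry, were run as alternatives. Ranges of adjusted p given for lists cover the other alternatives, with camera at the preset correlation, and leave these out. Counts of members past the test are also given adjusted over the list alone.

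The grouping, the test, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names 20 genes in advance. It adds the 10 largest rises and the 10 largest falls among genes past the threshold, with groups apart and a mean above the median gene, skipping predicted genes. It also adds up to 4 members of each list past the threshold, or up to 2 by smallest p where none passed. The alternatives were quantile normalization, centring on array medians, other pseudocounts, filters on dim genes, other choices of probe set, other variance models, array weights, the replicate number as a block, other thresholds, ordinary t statistics and leaving out each array in turn.

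Other choices were made after values had been seen. Lists of adipocyte, neutrophil, mesothelium and epithelium genes were written after the first look at the data. Orm1 of the adipocyte list had already been seen among genes that vary between arrays. A pair of alternatives that leave out genes of other cell types was added as well. The first of them also drops every gene that follows S100a8, Adipoq and Col3a1 over the 6 arrays at a correlation above 0.9. The milder one, limited to list members, was added after the first had left 3 changed genes. Matching of older symbols to list members was corrected after the list results had been seen, because 4 list symbols had been taken for other genes.

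The test by gene was tested on simulated arrays with the real means and spreads of the 18193 genes. It recovered 79.8% of genes changed by a log2 fold of 1 and 97.4% of those changed by 2, and 5.24% of its calls were false. camera called 15 of 15 simulated lists of 20 genes shifted by 0.5, and 1 of 150 unshifted lists. The simulation drew genes independently, gave each gene the same spread in both groups and changed few genes. It therefore does not test camera on correlated genes. The share of 5.24% is not an error rate of the calls on the real arrays, where spreads differed between groups. Spdef, for example, had a log2 SD of 0.03 in vehicle and 0.49 in DBZ arrays. Figures were drawn with matplotlib 3.10.9.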

Results

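Gene expression was measured in Lgr5-EGFP-high small intestinal stem cells sorted from 3 mice given vehicle and 3 mice given DBZ, 24 h after treatment. Lgr5 marks the stem cells at the base of the crypt, and DBZ blocks gamma-secretase, the protease complex that releases the active part of Notch receptors. The study compared the groups to find the expression signature of NOTCH1 inhibition in the mouse intestine. Array medians lay between 44.9 and 46.3 intensity units. Gene values correlated at 0.993 to 0.996 between vehicle arrays, 0.985 to 0.992 between DBZ arrays and 0.961 to 0.989 between groups, across genes, which are not independent replicates. The first principal component held 68.4% of the variance and separated the groups. The ratio of 3' to 5' signal of the actin control, a sign of RNA integrity, differed between the groups without overlap, at 2.22, 1.61 and 1.69 in vehicle replicates 1, 2 and 3 and 1.53, 1.51 and 1.57 in the DBZ arrays, and so moved with every comparison given here. That of the Gapdh control was 1.07 to 1.42 in vehicle and 1.05 to 1.09 in DBZ arrays, and overlapped.

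DBZ changed 972 of 18193 genes (5.34%; limma, Benjamini-Hochberg adjusted p under 0.05), of which 695 were higher and 277 lower. Among them 218 were at least 2-fold higher and 51 at least 2-fold lower. The groups did not overlap for 6031 genes, or 33.2%, where chance gives 10%. The largest fall among the named genes was that of Olfm4. The largest rise on the log2(intensity + 16) scale was that of Hp, and with a pseudocount of 1 it was exceeded by that of S100a8 (5.35 and 5.75). Of 33 gene lists tested with camera, 10 were called higher and 6 lower. With an estimated correlation 0 of the 16 calls held, while fry called 8 lists. The 8 were Notch targets, secretory regulators, goblet, enteroendocrine, reserve or revival stem cell, fatty acid oxidation, fibroblast and smooth muscle, and endothelial genes. Their adjusted p was 0.00099 to 0.047 (fry), against 0.054 for the endoplasmic reticulum list and 0.056 for S phase. The other lists called by camera had 0.11 or more (fry). Other splits of the 6 arrays into 3 and 3 called 6 to 18 lists with camera, so the count of 16 does not set the real grouping apart. The number of changed genes depended on single arrays: it was 49, 19 and 38 without vehicle replicate 1, 2 and 3, and 2032, 217 and 352 without DBZ replicate 1, 2 and 3. Of the 69 named genes past the threshold, 60, 61 and 57 lost the call without vehicle replicate 1, 2 and 3, and 1, 33 and 23 without DBZ replicate 1, 2 and 3. Olfm4, Hao2, Ccl9, Steap4, Gfi1, Hopx and Neurod1 kept it each time.

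Targets of Notch signalling fell. Olfm4, a secreted glycoprotein of crypt stem cells, dropped from 4346 ± 781 to 28.1 ± 8.81 intensity units (SD, n = 3), a log2 fold change of -6.63 ± 0.19 (SE; limma, Benjamini-Hochberg adjusted p = 0.00042). Its level in the DBZ arrays lay below the array median, so the size of the fall is uncertain, at -7.25 with a pseudocount of 1 and -5.57 with one of 64. Nrarp, a feedback inhibitor of Notch, fell from 514 ± 40.1 to 130 ± 37.4, and Hes1, the transcriptional repressor that Notch switches on, fell from 387 ± 50.5 to 213 ± 38 (SD, n = 3). Their log2 fold changes were -1.89 ± 0.19 and -0.82 ± 0.15 (SE; limma, adjusted p = 0.016 and 0.039). Dtx1 fell by 0.67, while Hey1 was at -0.22 ± 0.07 (limma, adjusted p = 0.12) and Myc at -0.01 ± 0.18 (limma, adjusted p = 0.99). Of the 11 listed targets 4 fell, or 5 adjusted over the list alone, with a median of -0.20 and a mean of -0.96 (camera, Benjamini-Hochberg adjusted p = 0.00061). The list had an adjusted p = 0.28 with an estimated correlation. Fibroblast and smooth muscle genes, described below as another cell type, were higher in the same arrays by a median of 1.03. Epithelium genes, a list written after the first look at the data, had a median of 0.02.

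Among 21 measured Notch pathway components, 2 rose and 2 fell. The ligand genes Dll1 and Dll4 rose by log2 folds of 1.33 ± 0.22 and 1.13 ± 0.12 (SE, n = 3). Notch1 fell from 327 ± 34.6 to 206 ± 31.9 intensity units (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0495), and Rfng, a glycosyltransferase that modifies Notch, fell by 0.69. Adjusted over the list alone, 3 rose and 2 fell, and the list was not called (camera, adjusted p = 0.84). None of the 5 measured gamma-secretase subunits passed the test (0 adjusted over the list alone; camera, adjusted p = 0.84). Aph1a was at -0.17 ± 0.12 and Psen2 at 0.12 ± 0.11, or -0.023 as the mean of its probe sets.

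**Figure D1:**
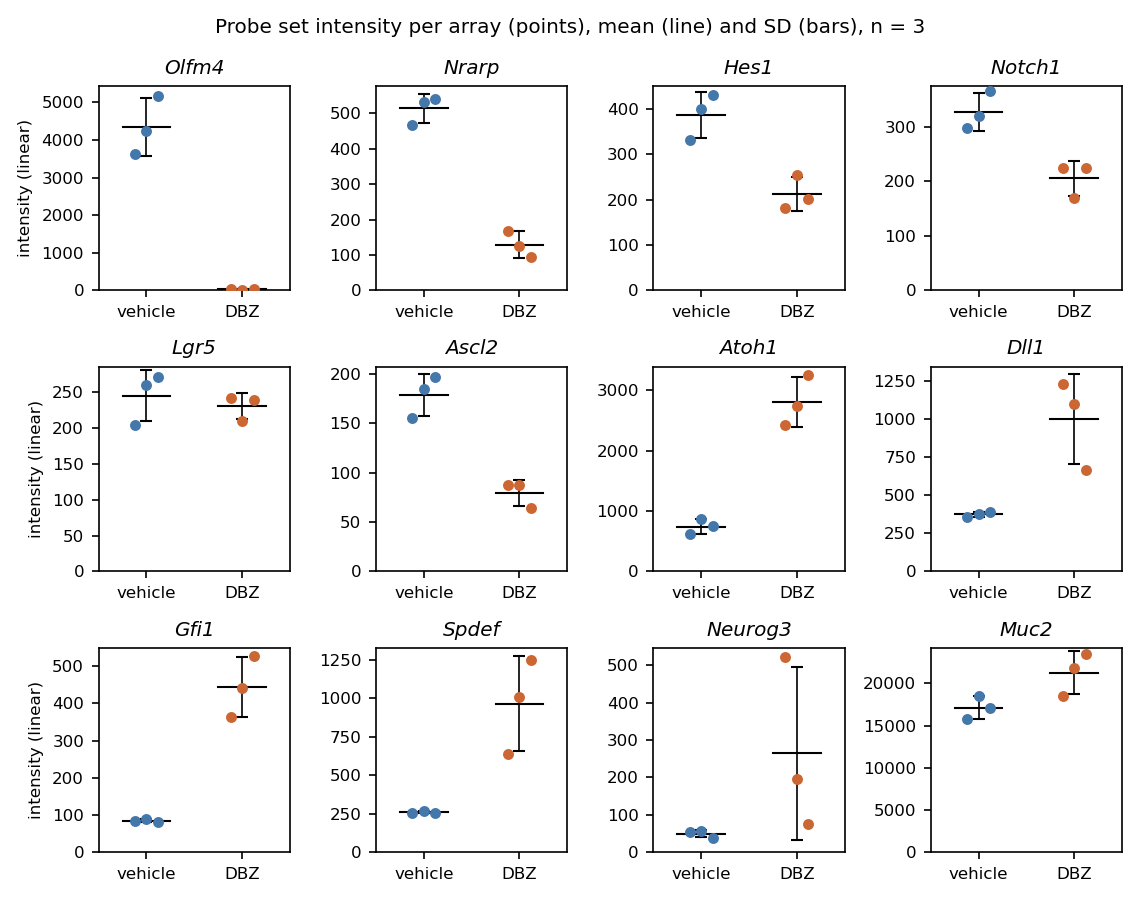
Linear probe set intensity of 12 named genes in each array (points), with group means (lines) and SD (bars, n = 3). Olfm4 averaged 4346 in vehicle and 28.1 in DBZ arrays, Atoh1 averaged 744 and 2810, and the groups overlapped for Lgr5.

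Regulators of the secretory lineage rose with DBZ. Atoh1, the transcription factor that commits crypt cells to secretory fates, went from 744 ± 128 to 2810 ± 416 intensity units (SD, n = 3), a log2 fold change of 1.90 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 0.0097). Gfi1, which acts downstream of Atoh1, rose by 2.17 ± 0.13, Neurod1 of the endocrine lineage by 1.84 ± 0.12 and the goblet cell factor Spdef by 1.78 ± 0.23. Of 20 measured regulators 11 rose and 0 fell, with 17 higher adjusted over the list alone and a median of 1.23 (camera, adjusted p = 5.3e-13). This list had an adjusted p = 0.16 with an estimated correlation. Neurog3, the master regulator of endocrine cells, averaged 264 ± 231 against 49.9 ± 9.51 (SD, n = 3) and did not pass (limma, adjusted p = 0.14). Mesenchymal genes were higher by a median of 1.03 in this comparison too. Each array measured all sorted cells together, and the goblet gene Muc2 and the Paneth gene Lyz1 averaged 17132 and 27046 in vehicle arrays. A rise within stem cells and a larger share of secretory cells in the sort cannot be told apart. This holds for the goblet, enteroendocrine and secretory machinery genes below as well.

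Goblet cell genes rose as well, 10 of 20 by the test over all genes and 16 adjusted over the list alone. Atoh1, Spdef and Creb3l1, all among the 10, are also in the list of secretory regulators. Neurod1 and Neurog3 of the enteroendocrine list are in it too, so these counts are not independent. Agr2, a disulfide isomerase needed for mucin production, rose by 1.46 ± 0.16, and Ccl9, a chemokine, from 484 ± 45.3 to 4950 ± 703 intensity units (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0012). Muc2, the main intestinal mucin, was already bright and stood at 0.31 ± 0.11 (SE; limma, adjusted p = 0.15). The list median was 1.08 (camera, adjusted p = 6.5e-12), with an adjusted p = 0.46 with an estimated correlation. Of 23 enteroendocrine genes 3 rose, Neurod1, Isl1 and Pcsk1, and 14 were higher adjusted over the list alone, with a median of 1.03 (camera, adjusted p = 6.4e-08, adjusted p = 0.46 with an estimated correlation). Chga was at 1.1 ± 0.32 (limma, adjusted p = 0.098). The mesenchyme median of 1.03 is close to those of both lists, which does not show a common source of these rises.

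Paneth and tuft cell lists were not called. Of 23 listed Paneth genes only 13 were measured, with Defa3 as the only defensin. Of these 13 genes 4 rose and 1 fell (4 and 3 adjusted over the list alone; median 0.06, mean -0.08; camera, Benjamini-Hochberg adjusted p = 0.49). Mmp7, which processes defensins, rose by 1.37 ± 0.23, Cd24a by 0.95 ± 0.12 and Wnt3, at low intensity, by 0.57 ± 0.06. The potassium channel gene Kcnn4 fell by 1.14. Outside the naming rule, Pla2g2a rose by 2.18 ± 0.39, while Ang4 was at -2.70 ± 0.66 and Mptx1 at -2.25 ± 0.53 (SE, n = 3). Ang4 and Mptx1 did not pass over all genes (limma, Benjamini-Hochberg adjusted p = 0.068 and 0.065). Adjusted over the list alone, both were lower (limma, adjusted p = 0.011 each). Lyz1, the Paneth lysozyme, lay near the ceiling of the arrays and was the brightest probe set of vehicle replicate 1, at 28128 intensity units, so the size of its difference, -0.30 ± 0.15 (SE, n = 3; limma, adjusted p = 0.26), is uncertain. None of 14 tuft cell genes passed (0 adjusted over the list alone; camera, adjusted p = 0.22), with Dclk1 at 0.87 ± 0.32, Trpm5 at 0.43 ± 0.10 and Avil at 0.91 ± 0.30. Without DBZ replicate 1 the tuft list passed (camera, adjusted p = 0.030; range over the alternatives at the preset correlation 0.030 to 0.49). With an estimated correlation it had an adjusted p = 0.77 (camera).

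Genes of the endoplasmic reticulum and the secretory machinery rose. All 24 were positive, 8 passed the test over all genes and 22 did so adjusted over the list alone, with a median of 0.68 (camera, Benjamini-Hochberg adjusted p = 9.4e-12). The list had an adjusted p = 0.46 with an estimated correlation. Pdia6, a disulfide isomerase, rose from 1719 ± 274 to 6020 ± 1908 intensity units (SD, n = 3), Sdf2l1 by a log2 fold of 1.54 ± 0.26, the signal peptidase subunit gene Sec11c by 0.98 ± 0.18 and the translocon gene Sec61b by 0.65 ± 0.11. Mesenchymal genes were higher in the same arrays by a median of 1.03.

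Stem cell markers moved apart. Lgr5 was at 245 ± 35.9 intensity units in vehicle and 230 ± 17.9 in DBZ arrays (SD, n = 3), a log2 difference of -0.08 with a 95% interval of -0.37 to 0.21 (limma, Benjamini-Hochberg adjusted p = 0.72). Cells of both groups were sorted on high GFP from the Lgr5 gene, which favours like Lgr5 levels. The value therefore cannot show whether DBZ changes Lgr5. Olfm4 fell as given above, Ascl2, a transcription factor of crypt base stem cells, fell by 1.03 and the water channel gene Aqp4 by 1.37. Rgmb, a co-receptor for bone morphogenetic proteins, rose by 0.79 ± 0.09, and Sox9 by 0.72 ± 0.10. Of 20 stem cell genes 4 rose and 3 fell (6 and 4 adjusted over the list alone), the median was 0.08 and the mean -0.23, and the list was not called (camera, adjusted p = 0.56). Genes used to mark reserve or revival stem cells rose in 3 of 7 cases, 4 adjusted over the list alone (median 0.38; camera, adjusted p = 0.014, adjusted p = 0.38 with an estimated correlation). These were Hopx, from 1607 ± 10.8 to 3602 ± 238 (SD, n = 3), Clu and Anxa1, and the mesenchyme median in these arrays was 1.03.

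Wnt target genes did not move as a group. Of 17 measured, 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.02; camera, Benjamini-Hochberg adjusted p = 0.16). Apcdd1 and Nkd1, both inhibitors of Wnt signalling, rose by 1.29 ± 0.11 and 0.72 ± 0.10 (SE, n = 3), Sox9 rose and Ascl2 fell. The other 3 probe sets of Nkd1 were at 0.04, -0.10 and 0.02, and the other 5 of Apcdd1 at 1.03, 0.93, 0.24, -0.04 and -0.06. Both values thus depend on the probe set. This list shares 8 genes with the stem cell list.

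DNA replication genes fell. Cdt1, a licensing factor of replication origins, went from 1248 ± 111 to 590 ± 148 intensity units (SD, n = 3), Gins2 and Gins1 of the replicative helicase fell by 0.84 and 0.82, and Chaf1b of chromatin assembly fell by 0.66. Of 29 S phase genes 8 fell and 0 rose, with 22 lower adjusted over the list alone and a median of -0.66 (camera, Benjamini-Hochberg adjusted p = 3.4e-11, adjusted p = 0.46 with an estimated correlation). Of 29 genes of G2 and mitosis 0 passed, also adjusted over the list alone (limma). Their median was -0.21 (camera, adjusted p = 0.045, adjusted p = 0.78 with an estimated correlation). That call ended without vehicle replicate 1 or 3 (camera, adjusted p = 0.23 and 0.15), without DBZ replicate 1 or 3 (0.069 and 0.54), with a pseudocount of 64 (0.055), without _x_at probe sets (0.052) and with array weights (0.36), in a range of 0.00011 to 0.54. The mesenchyme median in these arrays was 1.03. Mki67, a marker of dividing cells, was at -0.14 ± 0.18, Kif23 at -0.58 ± 0.16 and Cdca8 at -0.59 ± 0.23. None of 7 inhibitors of cyclin-dependent kinases passed (0 adjusted over the list alone; camera, adjusted p = 0.49). Cdkn1c was at 0.26 ± 0.12, Cdkn2b at -0.55 ± 0.22 and Cdkn2c at -0.16 ± 0.07.

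**Figure D2:**
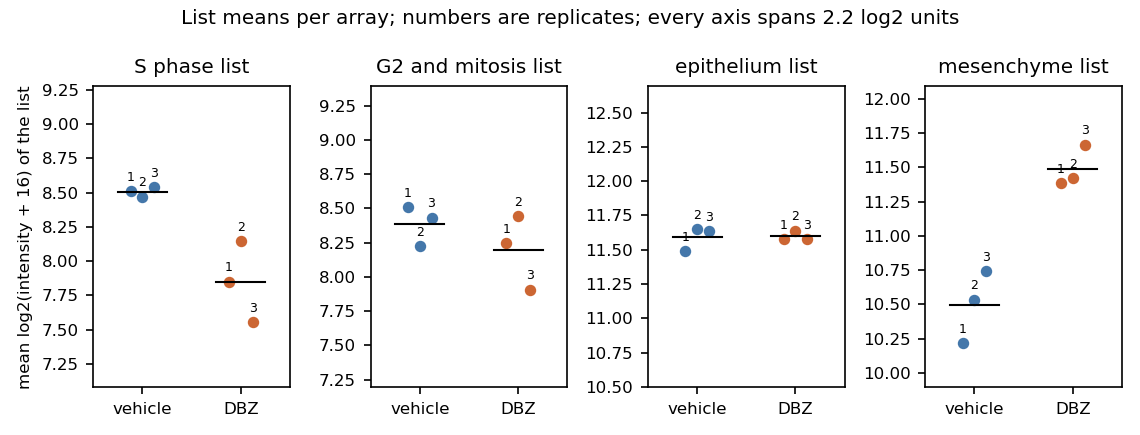
Mean log2(intensity + 16) of 4 gene lists in each array, with replicate numbers and group means (lines); each axis spans the same range. The S phase list averaged 8.47 to 8.54 in vehicle arrays and 7.55 to 8.15 in DBZ arrays, the G2 and mitosis values overlapped, and the epithelium list was written after the first look at the data.

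The lists of fatty acid oxidation, enterocyte and respiratory chain genes were called lower by camera, though not with an estimated correlation. Fatty acid oxidation genes were negative in all 15 cases, of which 2 fell by the test over all genes and 9 adjusted over the list alone, with a median of -0.64 (camera, Benjamini-Hochberg adjusted p = 7.5e-06, adjusted p = 0.46 with an estimated correlation). Slc25a20, the carnitine carrier of mitochondria, went from 2661 ± 305 to 1532 ± 100 intensity units (SD, n = 3), and Acot1 fell by 1.42. None of 22 enterocyte genes passed alone (0 adjusted over the list alone), while the list was called lower with a median of -0.38 (camera, adjusted p = 0.0027, adjusted p = 0.50 with an estimated correlation). Dgat1 was at -0.85 ± 0.27 and Lct, at low intensity, at -0.29 ± 0.07. Respiratory chain genes had a median of -0.16 with 0 of 24 past the test (0 adjusted over the list alone; camera, adjusted p = 0.0020, adjusted p = 0.71 with an estimated correlation), with Ndufv1 at -0.28 ± 0.07 and Ndufs1 at -0.27 ± 0.09. The mesenchyme median was 1.03 in the same comparison.

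Glycolytic genes had a median of 0.33, with 0 of 13 past the test over all genes and 2 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.032, adjusted p = 0.46 with an estimated correlation). Hk2 averaged 852 ± 300 in vehicle and 3193 ± 1834 in DBZ arrays (SD, n = 3; limma, adjusted p = 0.064), and Pgk1 was at 0.33 ± 0.08. The call ended without vehicle replicate 1 (camera, adjusted p = 0.16), without DBZ replicate 1 (0.073), with both filters on dim genes (0.099 and 0.13), without _x_at probe sets (0.063) and with array weights (0.13), in a range of 0.019 to 0.16. Mesenchymal genes were higher in the same arrays by a median of 1.03. Cholesterol synthesis genes were not called, with 0 of 16 past the test (0 adjusted over the list alone; camera, adjusted p = 0.19), Fdft1 at -0.37 ± 0.10 and Dhcr7 at -0.54 ± 0.17. Without vehicle replicate 1 and with array weights that list was called lower (camera, adjusted p = 0.032 and 0.017), in a range of 0.017 to 0.67.

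The neddylation pathway, named in the title of the series, showed no gene past the test among 21 measured (0 adjusted over the list alone; median 0.13; camera, Benjamini-Hochberg adjusted p = 0.12). Nedd8, the ubiquitin-like modifier itself, was at 2182 ± 156 and 2388 ± 101 intensity units (SD, n = 3), a log2 difference of 0.13 with a 95% interval of -0.05 to 0.31. Cand1 was at 0.32 ± 0.09 and Dcun1d5 at 0.57 ± 0.17. The list passed without vehicle replicate 2 (camera, adjusted p = 0.039; range 0.039 to 0.49). Of 25 ribosome biogenesis genes 1 rose, Tsr1, by 0.79 ± 0.14 (1 adjusted over the list alone; median 0.12; camera, adjusted p = 0.068). That list was called higher in 6 alternatives, among them without vehicle replicate 2 or 3 (camera, adjusted p = 0.048 and 0.045), without DBZ replicate 1 or 3 (0.0033 and 0.037) and with array weights, in a range of 0.0033 to 0.85. Of 15 p53 targets 1 rose, Phlda3, by 0.58 ± 0.07 (3 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.32).

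The 10 largest rises past the threshold, among genes with groups apart, a mean above the median gene and no predicted name, were those of Ccl9, given above, and of 9 genes in none of the lists. Hp, which encodes haptoglobin, rose from 58.5 ± 11.8 to 2570 ± 1101 intensity units (SD, n = 3), a log2 fold change of 5.02 ± 0.35 (SE; limma, Benjamini-Hochberg adjusted p = 0.0054). S100a8 and S100a9, abundant in neutrophils, rose by 4.97 ± 0.74 and 4.82 ± 0.78 from vehicle levels below the array median, 19.3 ± 4.08 for S100a8 (SD), so the size of these folds is uncertain, and both calls ended with a pseudocount of 64 (limma, adjusted p = 0.065 and 0.072; ranges 0.0043 to 0.10 and 0.0041 to 0.11). Saa3, an acute phase protein gene, rose by 3.85 ± 0.35. The metalloreductase gene Steap4 rose by 3.52 ± 0.21, Timp1, as uncertain in size from a vehicle level below the array median, by 2.81 ± 0.38 and Rnase1 by 2.56 ± 0.53. Car3 rose from 1052 ± 469 to 9292 ± 4274 and Adipoq, a hormone of fat cells, from 288 ± 176 to 1959 ± 1132 (SD, n = 3; limma, adjusted p = 0.027 and 0.047). With a pseudocount of 64 the calls of Timp1, Adipoq and Rnase1 ended as well (limma, adjusted p = 0.051, 0.071 and 0.083, in a range of 0.0053 to 0.15 over their alternatives). Among these 9 only Steap4 kept its call without each array in turn, and mesenchymal genes were higher in the same arrays by a median of 1.03.

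By the same rule, the 10 largest falls were those of Olfm4 and Nrarp, given above, and of 8 genes in none of the lists. Rdh7, a retinol dehydrogenase gene, fell from 501 ± 245 to 38.4 ± 17.9 intensity units, and Hao2, a peroxisomal oxidase gene, from 403 ± 87.3 to 36.6 ± 4.36 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.023 and 0.0041), in DBZ arrays to below the array median, so the size of both falls is uncertain. Fbp1 of gluconeogenesis fell by 2.72, the glucuronosyltransferase genes Ugt2b5 and Ugt2b35 each fell by 2.63, and the lipase gene Pnliprp2 fell by 2.32. Kcnq1 fell by 1.97 and Clic6 fell by 1.92. With a pseudocount of 64 the calls of Ugt2b5, Pnliprp2 and Kcnq1 ended (limma, adjusted p = 0.057, 0.065 and 0.051, in a range of 0.0088 to 0.13 over their alternatives). Members of the Ugt2b family are alike in sequence, so the values of these genes are uncertain.

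Markers of other cell types differed between the groups. Fibroblast and smooth muscle genes were positive in all 13 cases, with 8 higher over all genes and 12 adjusted over the list alone (median 1.03; camera, Benjamini-Hochberg adjusted p = 5.5e-10, adjusted p = 0.46 with an estimated correlation). Lum, an extracellular matrix proteoglycan gene, rose from 299 ± 86.7 to 1090 ± 133 intensity units (SD, n = 3), and Col1a2, Sparc and Des rose by 1.24 ± 0.14, 1.23 ± 0.18 and 1.20 ± 0.17. Of 10 endothelial genes 2 rose, Esam and Kdr, or 4 adjusted over the list alone (median 0.40; camera, adjusted p = 0.00028, adjusted p = 0.38 with an estimated correlation). Of 14 myeloid genes 0 passed over all genes, and 6 were higher and 1 lower adjusted over the list alone (median 0.64; camera, adjusted p = 0.018, adjusted p = 0.77 with an estimated correlation), with Adgre1 at 0.76 ± 0.22 and Itgax at -0.59 ± 0.17. The myeloid call ended without vehicle replicate 2 (camera, adjusted p = 0.090), without DBZ replicate 1 or 3 (0.067 and 0.15) and with array weights (0.36), in a range of 1.6e-05 to 0.36. Leaving out 120 genes of these and other non-epithelial lists, 16 of them past the threshold, left 959 changed genes, and also leaving out every gene that followed S100a8, Adipoq and Col3a1 over the arrays left 3. Both were chosen after the data had been seen.

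Lists of T cells, B cells, glia and neurons, major histocompatibility complex class II, interferon response and epithelial defence were not called (camera, Benjamini-Hochberg adjusted p = 0.086, 0.68, 0.086, 0.71, 0.23 and 0.84). In the first 5 of them 0 genes passed, also adjusted over the list alone. Gzma of intraepithelial lymphocytes was at -1.42 ± 0.42 and Cd7 at -0.69 ± 0.18, Cd79a at -0.26 ± 0.13, Ms4a1 at 0.17 ± 0.12, Snap25 at 0.82 ± 0.26, Elavl4 at 0.25 ± 0.07, H2-DMa at -0.38 ± 0.23, Ciita at -0.37 ± 0.34, Bst2 at 0.78 ± 0.20 and Ddx58 at -0.36 ± 0.11. Of 11 defence genes Lcn2 rose, from 67.3 ± 14.3 to 484 ± 272 intensity units, and Reg1 fell, from 90.6 ± 15.8 to 24.2 ± 3.18 (SD, n = 3), below the array median, the same 1 and 1 adjusted over the list alone. The T cell list was called lower in 6 alternatives, among them without vehicle replicate 2 (camera, adjusted p = 0.00073), without DBZ replicate 3 (0.021), with both filters on dim genes and with array weights, in a range of 0.00073 to 0.41. The interferon list was called higher without DBZ replicate 2 (0.0025, range 0.0025 to 0.94) and the glia list in 2 alternatives, among them without vehicle replicate 3 (0.045, range 0.036 to 0.20). Only 3 red blood cell genes were measured, too few for the test, with Hba-a1 at -0.17 ± 0.11 and Slc4a1 at -0.08 ± 0.07.

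Genes that respond to tissue dissociation were higher, 3 of 18 over all genes and 7 adjusted over the list alone (median 0.29; camera, Benjamini-Hochberg adjusted p = 0.0038, adjusted p = 0.46 with an estimated correlation). The heat shock genes Hspa1b and Hsph1 rose by 0.96 ± 0.11 and 0.48 ± 0.09 (SE, n = 3), and the immediate early gene Ier3 by 0.99 ± 0.18. With array weights the call ended (camera, adjusted p = 0.078; range 0.00022 to 0.078). The mesenchyme median in these arrays was 1.03.

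**Figure D3:**
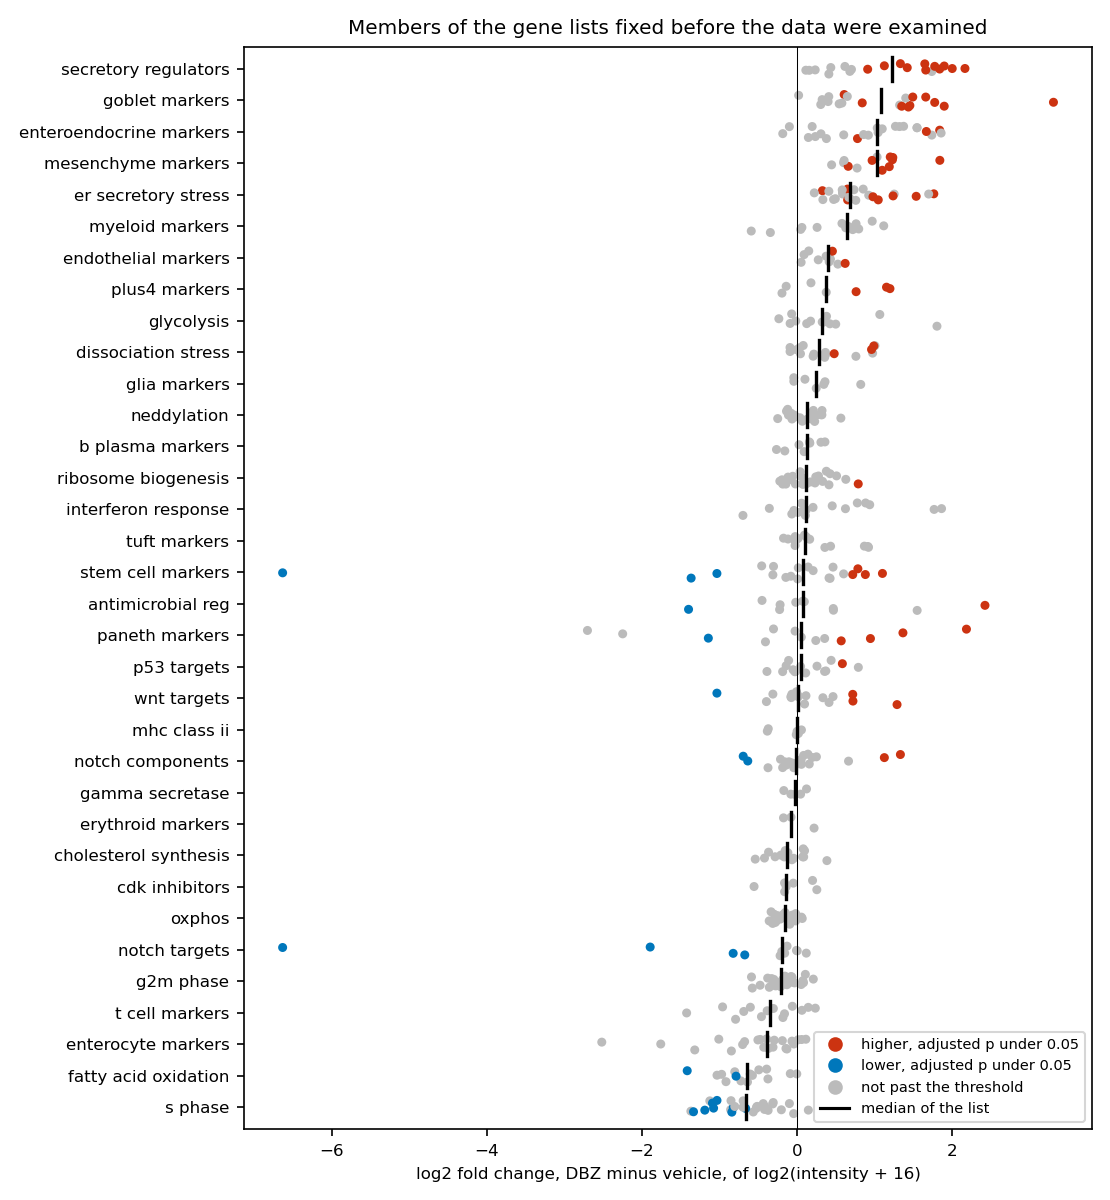
Log2 fold change, DBZ minus vehicle, of each measured member of the 34 gene lists (points; red higher and blue lower past the threshold, grey not) with list medians (bars). Secretory, goblet, enteroendocrine and mesenchyme lists have medians of 1.23, 1.08, 1.03 and 1.03, and the S phase list has the lowest, -0.66.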

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

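The test in this part was chosen only after the data had been seen. Probe sets without a single gene symbol were outside the comparison by gene. Of 10092 such probe sets, 3 were higher in the DBZ arrays than in the vehicle arrays and 1 was lower, in a limma fit over all probe sets with Benjamini-Hochberg adjustment over the unnamed ones. With the prior variance estimated from the unnamed probe sets alone, 23 were higher and 19 lower. Both fits were run, and the first was kept after both results had been seen, because it shares its prior with the named probe sets. The strongest of those higher rose from 59.1 ± 2.28 to 123 ± 5.83 intensity units and another from 66.4 ± 3.65 to 131 ± 2.47, while the one that was lower fell from 96.0 ± 16.1 to 18 ± 1.18 (SD, n = 3). They have no gene symbol in the table used here, and no explanation was tested.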

How the results depend on the processing

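Tests chosen after the data had been seen are the pair that leaves out genes of other cell types and the check of how its calls ended; the others were planned. The main counts are 972 changed genes, 695 higher and 277 lower, and 16 lists. With a pseudocount of 64 they were 440, 310 and 130, and with array weights 2690, 1660 and 1030. With the milder filter on dim genes 1470 changed, 438 of them lower. At an adjusted p under 0.10 the counts were 2575, 1642 and 933, and with a 2-fold minimum 269, 218 and 51. Ordinary t statistics called 0 changed, 0 higher and 0 lower genes after adjustment, with 3731 at an unadjusted p under 0.05, against 4790 in limma. An estimated correlation left 0 lists and fry 8. Leaving out 1 array gave 19 to 2032 changed, 16 to 1305 higher and 3 to 727 lower genes, and 15 to 18 lists. Fewer arrays lower the number of calls by construction; the cause of the rise without DBZ replicate 1 was not tested, nor was that of the other moves. All 972 genes kept their sign without each array in turn, and 18 kept the call.

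The other settings gave 769 to 1362 changed genes and 14 to 19 lists. Quantile normalization moved the share of higher calls from 71.5% to 62.9%. Leaving out 120 genes of other cell types left 959 changed genes. The first such alternative also left out every gene following S100a8, Adipoq and Col3a1, 1140 genes in all, and left 3 changed genes, 0 higher and 3 lower (Olfm4, Hao2 and Snx24). It removes 515 of the 695 higher genes, and choosing genes by markers that separate the groups cannot divide them by origin. The 457 changed genes it keeps, 180 higher and 277 lower, held their sign and an unadjusted p under 0.05, with adjusted p up to 0.097. The p-values of the fit of all genes, adjusted over the kept genes alone, also gave 3, so the other calls ended through the adjustment, with fewer small p-values in the set. The milder one was added after the value of 3 was seen.

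For named genes, 1544 of 1879 values stayed on their side of the threshold with the same sign, 289 lost the call and 42 gained one. Myc, at -0.01, ranged from -0.19 to 0.13 with 1 array left out and turned to 0.04 without vehicle replicate 2, 0.13 without vehicle replicate 3 and 0.08 without DBZ replicate 2, and Psen2 to -0.023 with the mean of its probe sets, neither past the threshold in any of these.

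With the replicate number as a block, 889 genes changed, 672 higher and 217 lower, and 19 lists were called. Beside the 16, these were ribosome biogenesis and glia, higher, and T cells, lower (camera, Benjamini-Hochberg adjusted p = 0.025, 0.036 and 0.0020; ranges 0.0033 to 0.85, 0.036 to 0.20 and 0.00073 to 0.41). The deviations of same-numbered arrays correlated at -0.01, 0.25 and 0.20, not all above 0.1, so the numbers are not taken to pair the mice. With DBZ arrays of other numbers, vehicle replicates 1, 2 and 3 reached at most 0.011, -0.0018 and 0.014. A factor shared by the arrays numbered 2, or by those numbered 3, is therefore not excluded.

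Of the 10 splits of the 6 arrays into 3 and 3, the real one included, 1 gave as many changed, 1 as many higher and 1 as many lower genes, and 2 gave as many lists. The highest other split gave 0 genes and 18 lists, and 10 splits are too few for a share under 0.05. The other splits called 6 to 18 lists with camera at the preset correlation, so the number of lists called does not set the real grouping apart. Without detection calls, the level at which dim genes carry signal is unknown.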

Other observations

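All tests and gene choices in this part followed a first look at the data; the limits for the fat, neutrophil and mesothelium lists were set before those lists were measured, apart from Orm1, and those for the other tests after their results had been seen. Genes past the threshold without each array in turn include 11 that the naming rule did not choose. Bhlha15, a transcription factor of mature secretory cells, was at 1.93 ± 0.13, Ptpro at 1.97 ± 0.13, Pcolce, an enhancer of collagen processing, at 1.68 ± 0.10 and Ccl12 at 1.72 ± 0.11 (SE, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0046, 0.0046, 0.0041 and 0.0046). Hpd, Selenom, Tspan4, Nrep, Adamts9 and Gpr146 were higher too, and Snx24 was lower, at -0.99 ± 0.07.

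Of 28 measured genes of the added epithelium list 1 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of 0.02. Tmprss2, a membrane protease gene, rose from 971 to 3281 intensity units on average, Klf5 fell from 6127 to 4171 and Marveld2 from 547 to 378. Epcam was at 0.03 ± 0.08. The camera p of the epithelium list was 0.71, unadjusted.

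S100a8 and S100a9, known from neutrophils, and Adipoq, known from fat, were among the 10 largest rises named in the DBZ arrays, although the GFP sort should remove such cells, and genes of the peritoneal lining were tested with them. Other neutrophil genes had a median of 0.16 (bootstrap 95% interval 0.03 to 0.39), and a camera p of 0.034 unadjusted, or 0.41 with an estimated correlation, which neither meets nor excludes the limit of 0.3, and 2 of 17 lay above the median gene in vehicle. Mesothelial genes had a median of 0.73 (0.52 to 1.18), and 7 of 18 lay above the median gene in vehicle. Of the 18 genes 5 were higher, or 9 adjusted over the list alone. Krt7 went from 1583 to 3652, but the brightest, Crip1, near the ceiling of the arrays, from 25238 to 22681. Wt1, Muc16, Bnc1, Lrrn4 and Rspo1 were positive but averaged below the array median in both groups, and none of them passed over all genes. RNA of mesothelial cells may therefore contribute. Adipocyte genes had a median of 0.44 (-0.03 to 1.01), or 0.31 without Orm1, with 1 of 16 higher (Plin4), 4 higher and 1 lower adjusted over the list alone, Pparg at -0.06, and 11 of 16 above the median gene in vehicle. Both lists met the limit with a preset correlation (camera, unadjusted p = 2.9e-05 and 0.012) and neither passed with an estimated one (p = 0.15 and 0.28), and a response of the sorted cells to DBZ stays open and untested.

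DNA replication genes were lower in the DBZ arrays. A lower share of epithelial cells would lower epithelial genes alike, but the epithelium median lay 0.68 above that of the S phase list (bootstrap 95% interval 0.37 to 0.89). The brightest epithelium genes, with Krt8 at 23442 and Lgals4 at 20897 in vehicle arrays, lay towards the ceiling of the arrays, where a fall may be compressed. A compressed fall would still be negative, yet 15 of 28 epithelium genes were positive. Their median was 0.02 (bootstrap 95% interval -0.16 to 0.09), against -0.66 for the S phase list. These values argue against a lower share of epithelial cells as the source of the whole S phase fall. A smaller decrease of that share is not excluded. An even fall of all cell cycle genes is argued against, since the G2 and mitosis median lay 0.45 above that of the S phase list (0.22 to 0.68). Both intervals resample genes as if they were independent. In DBZ replicates 1, 2 and 3 the S phase list averaged 7.85, 8.15 and 7.55 and the mesothelium list 7.74, 7.38 and 8.07, in opposite order. The fat and neutrophil lists were ordered as the mesothelium list. The mesenchyme list, at 11.38, 11.42 and 11.67, was in neither order, and 3 arrays are too few to test this. A part played by RNA of other cells and a change in the share of cells in S phase under DBZ are candidate explanations that stay open.

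A label field names DMSO for all 6 arrays. If a mislabelled sample lay behind this, with the 3 arrays titled DBZ holding vehicle RNA, genes that Notch drives would not separate the groups. All 3 of Olfm4, Nrarp and Hes1 were past the threshold with no overlap between the groups, which argues against it. For these genes no array of either group lay among those of the other.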
